A study of Mus musculus with 2 samples.

How the data were processed

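The samples were 2 mouse duodenum libraries, 1 wild type and 1 with Gsdmd deleted in the intestinal epithelium by Villin-cre, prepared from dissociated tissue with a droplet kit that tags the 3′ end of each transcript. The number of animals behind each library is not given in the sources used here. The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, without normalization by the authors. Per the file headers the matrices were written by Cell Ranger 5.0.0, whereas per the submitters' processing notes Cell Ranger 3.1.0, Seurat 4.0.1 and the mm10 genome were used. The lowest total of a barcode was 501 UMIs in the wild-type and 500 UMIs in the knockout file. Of 30568 gene IDs in the files, 30498 were found in the GENCODE annotation of GRCm38 from which coordinates were taken.

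Barcodes with at least 500 genes and at most 25% mitochondrial UMIs were kept, which left 4312 of 8996 wild-type barcodes (47.9%) and 3965 of 12336 knockout barcodes (32.1%). Fewer than 500 genes were counted in 2080 wild-type and 5667 knockout barcodes. Doublets were predicted in each library with Scrublet as run by scanpy 1.11.5, and 43 wild-type and 39 knockout barcodes were left out (0.997% and 0.984%, against 7.20% and 9.87% that 0.8% per 1000 barcodes would give). Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1 gave 32 clusters over both libraries together. Clusters were named from lists of markers of 26 cell types fixed before the data were examined, by the mean log2 fold of the markers and by the markers among the 10 genes with the largest fold. The rule that turned scores into names was set after the clusters were seen. Classes are called enterocyte-like, goblet-like and so on, and the 5 classes with at least 50 cells in each library were compared.

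UMIs were summed over the cells of each class and library and divided by the sum's total (CPM). Each log2 ratio of knockout over wild type has an exact conditional binomial 95% interval, each CPM an exact Poisson interval and each share of cells an exact Clopper-Pearson interval. These cover counting error only, and no test between genotypes was made, since cells of 1 library are not replicates. A gene at 0 in 1 library was set to a floor of 3 counts. Of 30 gene lists fixed before the data were examined, the median ratio was taken over members with at least 20 summed UMIs where at least 5 remained, and was placed among 10000 random lists of the same size matched on expression, as a description of these libraries. Genes were named by a rule fixed before the data were examined: in enterocyte-like cells the 12 largest and the 12 smallest ratios among genes with at least 100 UMIs and 50 CPM in either library whose interval excludes a 1.5-fold difference, in other classes 3 and 3, and in each list described up to 4 members with at least 50 UMIs and the largest absolute ratios. The rule passed over mitochondrial and ribosomal protein genes and immunoglobulin variable segments. All MHC class II members and Gsdmd were named in any case, and genes named beyond the rule were chosen after their values were seen. In the enterocyte-like cells every list with a median is given. The lists described by their members, and the lists given in the other classes, were chosen after the values were seen.

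RNA set free by broken enterocytes enters other droplets. Its share in a class was estimated from enterocyte markers with at least 500 CPM in enterocytes as the median ratio of their levels, which takes all enterocyte marker RNA in that class as free RNA. It came to 4.27% of the UMIs of wild-type and 6.00% of knockout T cell-like cells, and 8.65% and 9.71% in crypt stem/progenitor-like cells. In goblet-like cells it came to 39.7% and 42.2%, and in tuft-like cells to 8.09% and 15.6%. Markers that a class expresses itself, or mixed droplets, would raise this estimate. Wild-type goblet-like cells had Reg3b at 953 CPM, below the 1603 CPM that the estimate gives. The free RNA levels given below rest on this estimate and may be too high. The share of a gene's UMIs held by its top cell was computed to find values that rest on 1 cell.

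Alternatives were a looser filter (200 genes, 50% mitochondrial UMIs) and a stricter one (1000 genes, 10%), doublets kept, Leiden resolutions of 0.5 and 2, scaling of genes within each library, clustering without the listed genes, and thinning of cells to 2000 UMIs. For ratios they were a median-of-ratios size factor, totals without mitochondrial and ribosomal protein genes, the mean of CPM per cell, and for lists a minimum of 100 UMIs, or no minimum together with log2 of CPM + 1. After the data were seen 3 more were added: the expected share of doublets left out, the median over enterocyte clusters with at least 20 cells of each library, and enterocytes matched on mitochondrial share in steps of 5% and UMIs in steps of 0.5 on the log2 scale. The scaling choices shifted the median log2 ratio of all genes in goblet-like cells from -0.12 to 0, and in enterocytes from -0.09 to -0.11 with totals without mitochondrial and ribosomal protein genes. The procedure was tested on simulated data of 10899 genes with 200 changed: all genes changed 4-fold and 96% of those changed by a factor of 2 passed the size rule in either direction, no unchanged gene did, and 95.3% of the intervals held the true ratio. The counts were drawn with Poisson error alone, at the depth of all cells that passed the filter. Coverage near 95% was therefore built in, and variation between cells or animals and the lower depth of single classes were not simulated. The computations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2 and matplotlib 3.10.9.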

Results

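Gasdermin D, the product of Gsdmd, is a protein that forms pores in membranes after cleavage by inflammatory caspases. The comparison asked how the cells of the small intestine differ when the gene is deleted in the intestinal epithelium by Villin-cre. RNA of single cells from mouse duodenum was counted in 1 wild-type library and 1 library of the conditional knockout, both from the same batch per the labels. The wild-type library held 8996 barcodes and 87349543 UMIs (counted RNA molecules), and the knockout library held 12336 barcodes and 95446366 UMIs. The median barcode had 6202.5 UMIs and 24.6% mitochondrial UMIs in the wild-type library, against 2852 UMIs and 45.6% in the knockout library. After the filters and the removal of predicted doublets, 4269 wild-type and 3926 knockout cells remained, with medians of 10240 and 8499.5 UMIs and of 11.4% and 8.57% mitochondrial UMIs. With 1 library per genotype, no difference below has a replicate check: each describes these libraries, and each interval is a 95% interval that covers counting error only, unless another source is named. Ratios are given as log2 of knockout over wild type, and levels as CPM, a gene's UMIs scaled to the total of the summed cells of a class.

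Gsdmd was lower in the epithelial cells of the knockout library. The gene (ENSMUSG00000022575, plus strand of chromosome 15, 75862327 to 75867408 in GRCm38) reached 226 CPM (222 to 230) in wild-type epithelial cells and 58.8 CPM (56.8 to 60.8) in knockout epithelial cells, a log2 ratio of -1.94 (-1.997 to -1.89). The knockout level was 26.0% of the wild-type level. In cells outside the epithelium, where Villin-cre is not active, Gsdmd stood at 41.8 CPM (37.0 to 47.2) and 26.5 CPM (22.5 to 30.9), a log2 ratio of -0.66 (-0.95 to -0.37). T cell-like cells made up most of these, with 41.9 and 26.3 CPM, of which free RNA of enterocytes would give 10.8 and 4.13 CPM. The libraries were counted at the 3′ end of each transcript, so transcripts that lack the deleted exons but keep their 3′ end would still be counted.

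Enterocyte-like cells, the absorptive cells of the villus, were the most numerous class in both libraries with the filters used and took a smaller share of the kept cells in the knockout library. They made up 63.0% (61.5 to 64.4) of 4269 wild-type cells and 56.0% (54.4 to 57.5) of 3926 knockout cells, a difference of -7.01 points. Crypt stem/progenitor-like cells made up 1.83% (1.45 to 2.28) and 3.39% (2.84 to 4.00), and goblet-like cells, which secrete mucus, 2.97% (2.49 to 3.53) and 3.95% (3.36 to 4.61). T cell-like cells made up 27.3% (25.9 to 28.6) and 26.1% (24.7 to 27.5), and tuft-like cells, chemosensory cells of the epithelium, 1.55% (1.198 to 1.96) and 1.66% (1.28 to 2.11). Among epithelial cells alone, 3017 in the wild-type and 2592 in the knockout library, enterocyte-like cells made up 89.1% and 84.8%, crypt-like cells 2.59% and 5.13%, goblet-like cells 4.21% and 5.98%, and tuft-like cells 2.19% and 2.51%. The enterocyte difference turned to 8.08 points higher in the knockout library with a stricter cell filter, and the T cell-like difference grew to -14.07 points. The goblet-like difference of 0.973 points was 0.0101 points with that filter and 3.45 points with a looser one. With the stricter filter T cell-like cells outnumbered enterocyte-like cells in the wild-type library, 862 to 518.

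The remaining classes were too small for a comparison of genes. Plasma cell-like cells made up 0.586% of wild-type and 1.96% of knockout cells, a cluster named fibroblast-like 0.328% and 1.86%, and macrophage or monocyte-like cells 0.375% and 1.15%. The fibroblast-like cluster also had the endothelial marker Plvap among its top genes. At Leiden resolution 2 it split into 6 and 18 fibroblast-like and 8 and 55 blood endothelial-like cells, and with the looser filter or the expected share of doublets left out it was named blood endothelial. Dendritic cell-like cells made up 0.398% and 0.560%, and enteroendocrine-like cells, the hormone-secreting cells of the gut, 1.36% (58 cells) and 1.07% (42 cells). A further 16 wild-type and 92 knockout cells, 0.375% and 2.34%, were left unnamed. Of these, 2 and 69 lay in a cluster with no class near it, and 14 and 23 in a cluster that scored highest for dendritic cells but had more macrophage or monocyte markers among its top genes, beside H2-Eb1, Cd74 and H2-Aa.

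**Figure D1:**
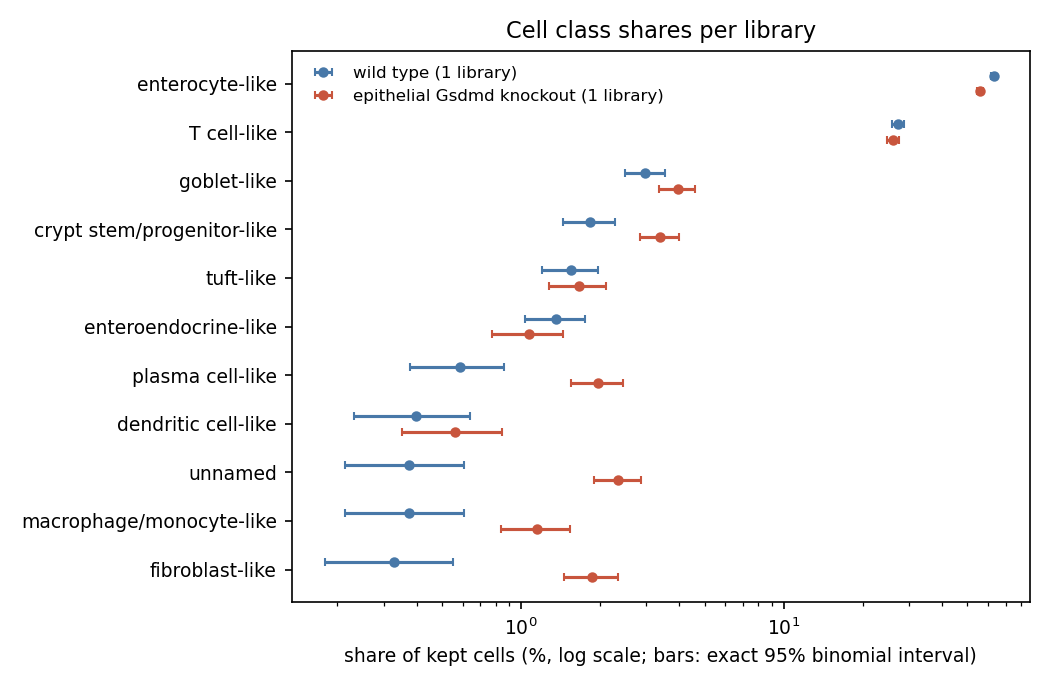
Share of kept cells taken by each class in the wild-type library (blue) and the epithelial Gsdmd knockout library (red), in percent on a log axis, with exact 95% binomial intervals as bars. Enterocyte-like cells took 63.0% and 56.0%, and crypt stem/progenitor-like cells 1.83% and 3.39%.

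In the enterocyte-like cells, genes that present antigen on MHC class II were lower in the knockout library. All 8 measured members of the list were lower by at least 1.5-fold, and the list's median log2 ratio of -1.92 lay below all 10000 random lists matched on expression. H2-Aa (ENSMUSG00000036594, minus strand of chromosome 17, 34282744 to 34287823), which encodes the alpha chain of I-A, was at 919 CPM in wild-type and 152 CPM in knockout enterocytes (-2.60, -2.63 to -2.56). Its partner H2-Ab1 was at 1072 and 270 CPM (-1.99), H2-Eb1 at 377 and 105 CPM, and Cd74, the invariant chain that guides class II molecules through the cell, at 2602 and 727 CPM (-1.84). Ciita, the transcriptional activator of these genes, was at 27.6 and 4.78 CPM (-2.53, -2.74 to -2.32). H2-DMa and H2-DMb1, which load peptides, stood at -1.70 and -1.74, H2-DMb2 at 0.726 and 0.0431 CPM, and H2-Oa and H2-Ob had too few UMIs.

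The libraries' enterocytes lay mainly in different clusters of the main clustering, from which the listed genes were not left out. Clusters 1, 3, 7 and 6 held 25.2%, 19.4%, 16.1% and 10.2% of the wild-type enterocytes, whereas clusters 4, 5, 8 and 6 held 22.0%, 18.5%, 16.6% and 9.51% of the knockout enterocytes. A summed value of the class therefore compares different mixtures of these clusters, which may themselves be split by the genes compared. Cluster 1 held 678 wild-type and 15 knockout cells. Cluster 10, with 146 wild-type and 163 knockout cells, had medians of 2396 UMIs and 0.839% mitochondrial UMIs. The globin genes Hbb-bs and Hba-a1 were among its top 10 genes, and its cells are counted in the enterocyte shares and sums. When clusters were formed without the listed genes, 10 of 11 enterocyte clusters held at least 20 cells of each library. Cluster 1 of that clustering held 655 wild-type and 175 knockout cells, and its cluster 3 held 298 and 423. Over these 10 clusters the class II median was -2.37.

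Part of the genes that respond to interferon were also lower in knockout enterocytes. The MHC class I list had a median of -0.63 over 12 genes, 6 of them lower by at least 1.5-fold and none higher. The interferon response list had a median of -0.60 over 18 genes, 9 lower, 1 higher and 8 within that size. Both medians lay below all random lists. Gbp2, a guanylate-binding protein, was at 35.8 and 3.60 CPM (-3.31), Igtp at 563 and 139 CPM (-2.01), Irgm1 at 156 and 37.9 CPM (-2.05), and Gbp7 at -1.71. On the class I side, H2-Q7 stood at -1.56, Nlrc5, the activator of class I genes, at -1.15, Tap1, which carries peptides into the endoplasmic reticulum, at -1.02, and H2-D1 at -0.96. The interferon response median was -0.19 over the shared clusters and -0.26 between cells matched on mitochondrial share and UMIs. Both lay inside the central range of random lists for the whole class, but no random lists were drawn for these settings.

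Antimicrobial lectins were higher in knockout enterocytes. Of 13 measured antimicrobial genes 7 were higher and 1 lower by at least 1.5-fold, with a median of 1.09, above all random lists. Reg3b (ENSMUSG00000071356, plus strand of chromosome 6, 78370657 to 78373466), a secreted lectin of the gut epithelium, was at 4034 CPM in wild-type and 43439 CPM in knockout enterocytes, 10.8-fold (3.43, 3.42 to 3.44). Reg3g, which binds bacterial cell walls, was at 3320 and 13307 CPM (2.00), Reg1 at 8667 and 20640 CPM (1.25), and Reg3a at 43.8 and 117 CPM (1.42). Lcn2 and Duoxa2 stood at 3.27 and 1.53 from levels of 0.384 and 5.34 CPM in the wild type, with 41.9% of the knockout Lcn2 UMIs in 1 cell. The list's median was 0.31 when the minimum was dropped and every member was taken as log2 of CPM + 1.

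Genes known from the villus bottom were higher and genes known from the villus top lower in knockout enterocytes. The villus bottom list, which shares Reg1, Reg3b, Reg3g and Lypd8 with the antimicrobial list, had a median of 1.63 over 8 genes, 5 of them higher by at least 1.5-fold. Il18, a cytokine of the interleukin 1 family, was at 89.1 and 464 CPM (2.38, 2.33 to 2.43), and Gpx2, a glutathione peroxidase of the gut, at 163 and 763 CPM (2.23). The villus top list had a median of -0.57 over 9 genes, 4 of them lower by that size. Enpp3 stood at -1.02, Neat1 at -0.91, Ada, adenosine deaminase, at 7562 and 4223 CPM (-0.84), and Slc28a2 at -0.59. The villus top median was -0.26 over the shared clusters and -0.14 between matched cells. Both lay inside the central range of random lists for the whole class, but no random lists were drawn for these settings. Within the single shared clusters the villus bottom median ranged from 0.71 to 2.21.

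Genes against oxidative stress were higher in knockout enterocytes, 6 of 13 by at least 1.5-fold and 1 lower, with a median of 0.36. The metal-binding metallothionein Mt1 was at 457 and 2631 CPM (2.52), and the glutathione transferases Gstm1 and Gsta4 both stood at 1.48. Of 18 gasdermin and inflammasome genes 3 were higher and 3 lower, with a median of 0.10. Apart from Il18 and Gsdmd, the inflammasome adaptor Pycard stood at 0.75. The epithelial cytokine list had a median of 0.32 over 11 genes, 4 higher and 2 lower, with Ccl20, which draws Ccr6-bearing lymphocytes, at 18.6 and 52.7 CPM (1.51), Il33 at 0.95 and Cxcl9 at -0.86, although 50.5% of the knockout Cxcl9 UMIs came from 1 cell.

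Genes of lipid absorption, of cholesterol synthesis and of iron, calcium and vitamin uptake were lower on balance in knockout enterocytes. The lipid absorption list had a median of -0.36 over 21 genes, 5 lower and none higher by at least 1.5-fold, with the fatty acid transporter Slc27a4 at -0.82, the lipoprotein receptor Scarb1 at -0.70, the apolipoprotein Apoa1 at 23609 and 14649 CPM (-0.69) and the sterol exporter Abcg8 at -0.66. Cholesterol synthesis stood at -0.38 over 12 genes, 5 of them lower by that size, with Sqle at -0.78, Cyp51 and Insig1 at -0.71 and Hmgcs1 at -0.63. Iron, calcium and vitamin uptake stood at -0.31 over 13 genes, 4 lower and 1 higher, with the ferric reductase Cybrd1 at 633 and 202 CPM (-1.65), the calcium channel Trpv6 at -1.28, the iron transporter Slc11a2 at -0.92 and the vitamin D receptor Vdr at -0.88. Carbohydrate digestion and uptake had 2 of 12 genes lower and 2 higher, and a median of -0.14 inside the central range of random lists. Its gluconeogenic enzymes went both ways, with Pck1 and G6pc at -2.49 and -1.08 and Fbp1 at 0.68, and the disaccharidase Sis stood at 0.86. Peptide and amino acid uptake had 1 of 14 genes lower and 3 higher, with a median of 0.07 that changed sign under the stricter filter.

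Early response and dissociation stress genes had a median of -0.51 over 15 genes, below all random lists, with Hspa1a at -1.97, Egr1 at -1.21, Hspa1b at -1.19 and Jun at 471 and 221 CPM (-1.09). The median of this list was -0.19 between matched enterocytes, and it was below 0 in the other classes too, at -0.38 in crypt stem/progenitor-like, -0.54 in goblet-like, -0.34 in tuft-like and -0.27 in T cell-like cells. Junction and barrier genes had a median of -0.34 over 14 genes, with Cgn at -0.52, Cldn4 at -0.49 and Epcam at -0.44, whereas Cldn2, a pore-forming claudin, was at 10.7 and 28.2 CPM (1.40). Goblet and mucus genes stood at 0.92 over 9 genes and gut hormone genes at 0.59 over 8 genes. The goblet and mucus list also stood at 1.07 over 10 genes in T cell-like cells, and free RNA of goblet cells was not estimated. In the hormone list 96.7% of the knockout Nts UMIs, 86.1% of those of Cck and 71.9% of those of Pyy came from 1 cell, and the list's median turned to -0.15 with the expected share of doublets left out. Smaller medians were -0.01 for fatty acid oxidation and ketogenesis, 0.03 for xenobiotic and retinoid genes, 0.21 for endoplasmic reticulum stress, -0.14 for crypt and Wnt genes and 0.19 for proliferation. Tuft type 2 genes stood at -0.41, T cell effector and regulatory genes at 0.01, macrophage inflammatory genes at -0.46, apoptosis and necroptosis genes at -0.17 and nuclear oxidative phosphorylation genes at 0.18. Of these, only the medians for xenobiotic and retinoid genes and for apoptosis and necroptosis kept their sign under every alternative run. Immunoglobulin and sex-linked genes had fewer than 5 measured members in enterocytes.

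**Figure D2:**
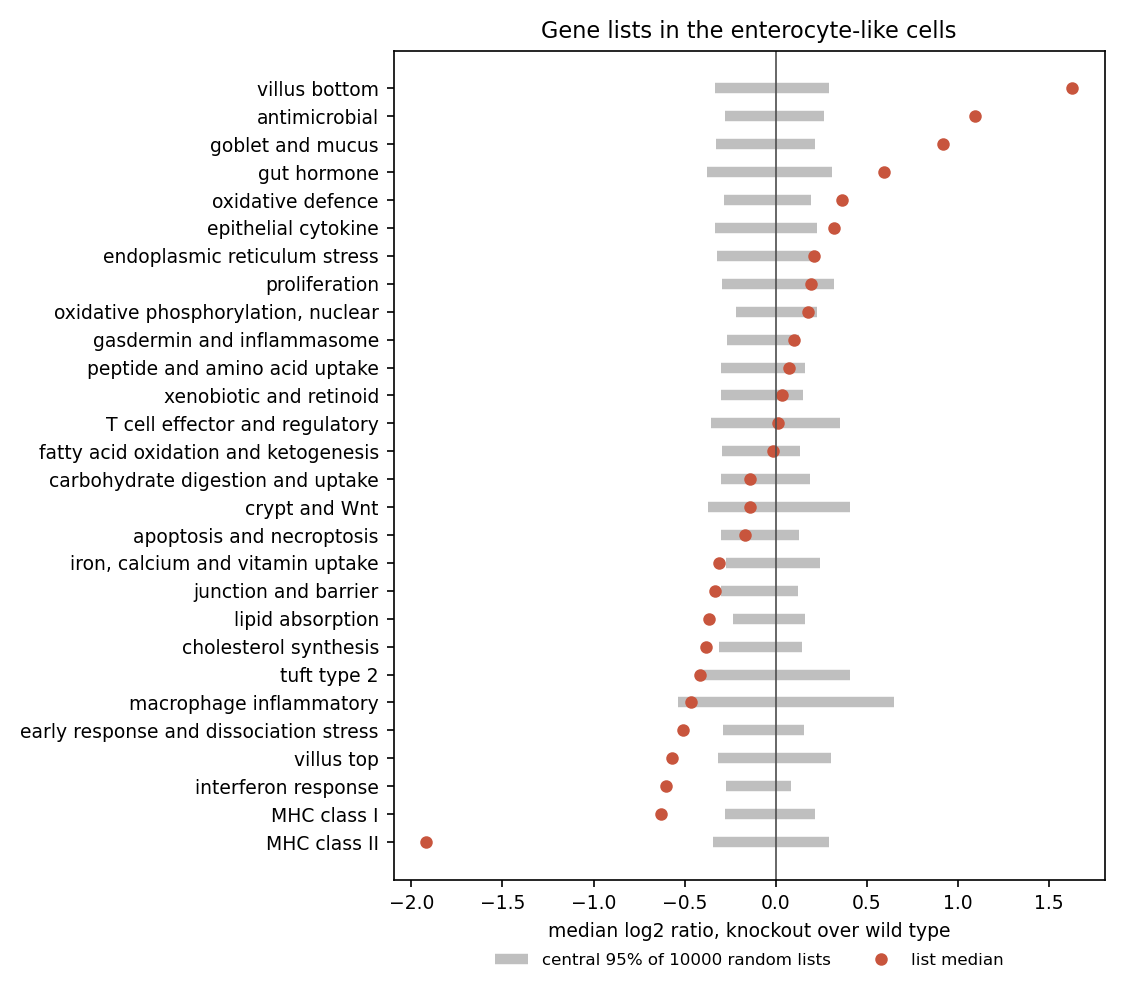
Median log2 ratio (knockout over wild type) of each gene list in the enterocyte-like cells (points), with the central 95% of 10000 random lists matched on expression (grey bands). The MHC class II list lies lowest at -1.92, and the villus bottom list highest at 1.63.

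Among single enterocyte genes outside these groups, Ubd, a ubiquitin-like protein induced by interferon, was lower in the knockout library, at 1399 and 189 CPM (-2.89, -2.92 to -2.86). The class I gene H2-Bl, annotated as a polymorphic pseudogene, was lower too, at 102 and 23.6 CPM (-2.11). The nuclease Dnase1 was at 179 and 53.4 CPM (-1.74) and Nckap5 at 70.2 and 20.6 CPM (-1.77). On the higher side, Aldh1a1, which makes retinoic acid, was at 33.7 and 99.2 CPM (1.56), and Akr1c19 at 26.2 and 69.8 CPM (1.41). The gene model Gm8797 (ENSMUSG00000103034, plus strand of chromosome 3, 5750806 to 5751295) was at 14.9 and 177 CPM (3.57), which is uncertain because other genes have near-identical sequence: 85.7% of its words of 31 bases also occur in Ubb. These genes and those named above include the 12 largest and the 12 smallest ratios that the rule for named genes gave. The median of all 9736 enterocyte genes was -0.09.

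Crypt stem/progenitor-like cells, 78 in the wild-type and 133 in the knockout library, also had lower MHC class II genes and higher stem cell genes in the knockout library. All 7 measured class II genes were lower by at least 1.5-fold, with a median of -1.39. H2-Aa was at 371 and 81.9 CPM, of which free RNA of enterocytes would give 79.5 and 14.8 CPM, and Cd74 was at 1768 and 864 CPM (-1.03). The crypt and Wnt list had a median of 0.83, with 9 of 13 genes higher by at least 1.5-fold and none lower. The stem cell marker Olfm4 was at 121 and 587 CPM (2.27), Axin2, a target of Wnt signalling, at 13.6 and 33.2 CPM (1.29), Slc12a2 at 87.4 and 197 CPM (1.17), and Ascl2 at 1.48 and 11.8 CPM (3.00), with all 5 wild-type UMIs in 1 cell. Class I genes stood at -0.68 and the interferon response at -0.28, with 7 of 18 genes lower, 5 higher and 6 within 1.5-fold, among them Igtp at 237 and 46.7 CPM (-2.35) and Ifitm3 at 190 and 414 CPM (1.12). Antimicrobial genes stood at 0.87, with 8 of 12 higher and 2 lower by that size, and Reg3b at 953 and 7760 CPM (3.03) against 349 and 4219 CPM that free RNA would give. Proliferation genes stood at 0.11, with the replication factor Mcm6 at 0.89, and cholesterol synthesis at -0.74, with 9 of 12 genes lower. Gm8797 (3.87) was the largest ratio in this class by the rule for named genes, followed by Zg16 (3.71), with 47.8% of the knockout UMIs in 1 cell. The lowest were the defensin Defa17 (-7.80), Spp1 (-6.33) and Itln1 (-4.89), for which 100%, 100% and 66.7% of the wild-type UMIs came from 1 cell. The cluster's top 10 genes, among them Ptma, Rps2, Hspd1, Ube2c, Hmgb2 and Dmbt1, held none of the 10 crypt markers. A larger share of stem cells in this cluster was not separated from a higher level of stem cell genes per cell.

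Goblet-like cells, 127 and 155, had mucus genes at like levels in both libraries. The goblet and mucus list had a median of 0.05 over 11 genes, with the mucus lectin Zg16 at 146704 and 175396 CPM (0.26), Agr2 at -0.21 and Retnlb at -0.78. Muc3 stood at 1.47, but enterocyte RNA alone would also give a higher Muc3 level in knockout than in wild-type goblet-like cells. The mucus median turned to -0.11 when every cell weighed the same. Class II genes stood at -2.31 over 7 genes, but H2-Aa, at 431 and 68.0 CPM, lay near the 365 and 64.1 CPM that enterocyte RNA, 39.7% and 42.2% of the goblet-like UMIs, would give. Reg3b, at 953 and 15084 CPM (3.98), lay below the 1603 and 18336 CPM from enterocyte RNA. Class I genes stood at -0.69, with H2-Q7 at -1.40, the interferon response at -0.26, with Gbp2 at 431 and 132 CPM (-1.70) against 14.2 and 1.52 CPM from enterocyte RNA, and cholesterol synthesis at -0.70, with Fdps at -1.13. Antimicrobial genes stood at -0.07, with 4 of 13 higher and 3 lower by at least 1.5-fold. Mt1 (2.40) and Gm8797 (3.51) were higher, but enterocyte RNA at its estimated share would give much of both. Mt1 was at 290 and 1526 CPM against 182 and 1111 CPM from enterocyte RNA, and Gm8797 at 12.5 and 142 CPM against 5.94 and 74.8 CPM. The Paneth cell defensins Defa30 (-9.41) and Defa39 (-3.85) were lower, with 71.7% and 69.7% of their wild-type UMIs in 1 cell. Defa38 had 374 UMIs in wild-type and 0 in knockout goblet-like cells, with an upper limit of -6.73 for the ratio, but 59.9% of its wild-type UMIs came from 1 cell. The median of all 4316 genes in this class was -0.12, and the ratios are to be read against it.

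Tuft-like cells, 66 and 65, had most type 2 genes within 1.5-fold in the libraries. The tuft type 2 list had a median of -0.21, with 2 of 12 genes lower by at least 1.5-fold, none higher and 10 between. Alox5ap and Ltc4s, of leukotriene synthesis, stood at 0.05 and 0.07. The members lower by that size were Il25, the cytokine through which tuft cells signal to lymphoid cells, at 53.6 and 28.9 CPM (-0.89) and the succinate receptor Sucnr1 at 24.1 and 13.7 CPM (-0.81), whose interval of -1.70 to 0.05 includes no difference. Mt1 was at 33.4 and 2983 CPM (6.48) against 37.0 and 409 CPM that free RNA would give, so only the knockout level lay above free RNA. Reg3b was at 134 and 10046 CPM (6.22) against 326 and 6757 CPM, and Il18 at 4.66 and 109 CPM (4.54) against 7.21 and 72.2 CPM, but 32.2% and 26.6% of their knockout UMIs came from 1 cell. The antimicrobial median of 3.64 over 6 genes included genes near free RNA in the knockout library, with Reg1 at 393 and 3569 CPM against 701 and 3210 CPM and Reg3g at 166 and 2864 CPM against 269 and 2070 CPM, and 39.4% of the knockout Reg3g UMIs came from 1 cell. Class II genes stood at -1.28, with H2-Aa at 66.1 and 12.4 CPM against 74.4 and 23.6 CPM from free RNA, class I genes at -0.34 and the interferon response at -0.28, with Gbp7 at -1.55. The lowest ratios by the rule for named genes, of Hbb-bs (-7.72), Fcgbp (-6.98) and Chgb (-6.41), came from single wild-type cells. These held 97.6%, 94.0% and 98.7% of the UMIs.

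T cell-like cells, 1164 and 1025, had lower summed levels of proliferation and cholesterol synthesis genes in the knockout library. The class was a different mixture of clusters in each library: cluster 12, with Hmgb2 and H1f5 among its top genes, held 14.3% of wild-type and 7.51% of knockout T cell-like cells, and cluster 9 held 9.71% and 19.6%. A smaller share of cycling cells was not separated from a lower level per cell. The proliferation list had a median of -0.68, with 11 of 16 genes lower by at least 1.5-fold in the knockout library and none higher. The nucleotide reductase subunit Rrm2 was at 80.3 and 40.5 CPM (-0.99), Top2a, a topoisomerase of dividing cells, at 319 and 173 CPM (-0.88), Mcm5 at -0.98 and Birc5 at -0.88. Cholesterol synthesis stood at -0.66, with 8 of 11 genes lower, among them Insig1 (-0.96) and Fdps (-0.73). T cell effector and regulatory genes stood at 0.08 over 18 genes, with the granule protease Gzmb at 9149 and 6498 CPM (-0.49), Cd69 at -0.42, the costimulatory receptor Icos at 4.70 and 12.7 CPM (1.44) and Maf at 0.98. The interferon response stood at 0.13, with Irgm1 at 0.41, Gbp2 at 0.33 and Isg15 at -0.55. Osteopontin, Spp1, was at 151 and 58.4 CPM (-1.37), and the gene model Gm47283 at 207 and 75.6 CPM (-1.45), both far above free RNA. Class II genes stood at 0.01, or -0.77 over members with at least 100 UMIs, with H2-Aa at 42.1 and 22.4 CPM against 39.2 and 9.11 CPM from free RNA. Antimicrobial genes stood at 1.44, with Reg3b at 86.4 and 2343 CPM (4.76) against 172 and 2606 CPM from free RNA, and Ubd at 80.3 and 15.9 CPM (-2.33) against 59.7 and 11.3 CPM. Mcpt2 (6.80) and Mcpt1 (6.17), proteases of mast cells, came from 1 knockout cell that held 99.8% and 99.5% of their UMIs.

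**Figure D3:**
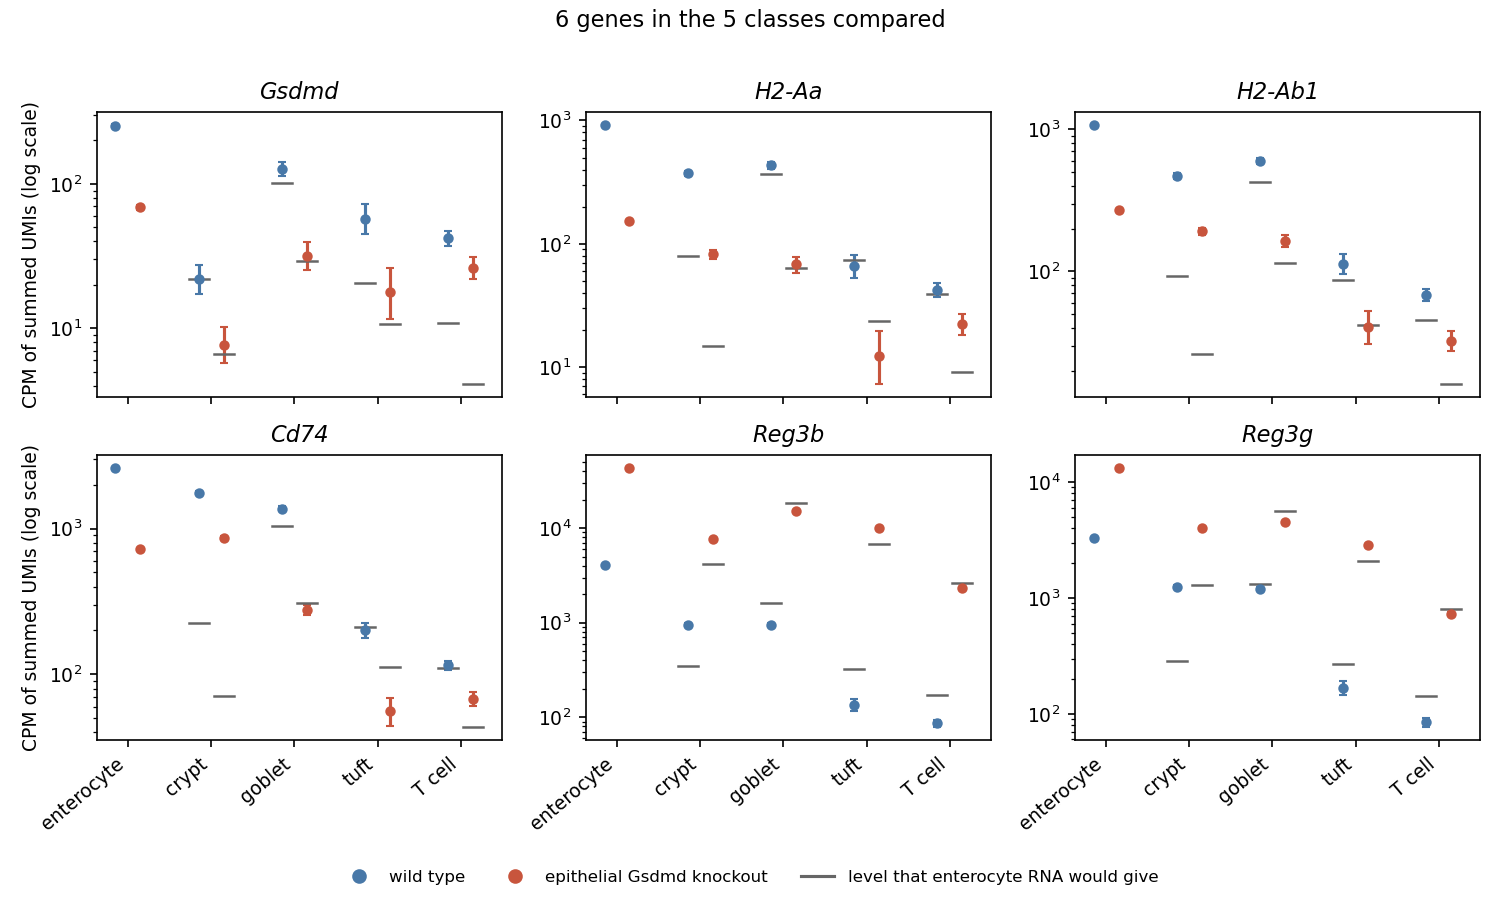
Levels of 6 genes in CPM on a log axis in the 5 classes compared, for the wild-type library (blue) and the epithelial Gsdmd knockout library (red), with exact 95% Poisson intervals and the level that free RNA of enterocytes would give (grey lines). H2-Aa lies above that level in crypt stem/progenitor-like cells, at 371 and 81.9 CPM, and Reg3b lies below it in T cell-like cells, at 86.4 and 2343 CPM.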

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

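The tests over shared clusters, in matched cells, of interferon-inducible genes, of Reg3b in T cells and of Gm8797 were chosen only after the result was seen, as was Reg3b among the genes of the barcodes left out. The bounds for antigen-presenting cell RNA and for matched cells were set before their values were computed, whereas the demand that the whole interval or range pass the bound was added after the values were seen.

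MHC class II genes were lower in knockout enterocytes, with a list median of -1.92. Different shares of clusters in the libraries do not account for the whole difference: over 10 shared clusters the median was -2.37. Its interval of -2.61 to -1.505, from order statistics, covers only the spread between clusters of these 2 libraries. Enterocyte states within these clusters may still differ. In all 10, the villus bottom median was higher in the knockout library (0.71 to 2.21) and the villus top median lower (-0.99 to -0.10). This test therefore cannot exclude a difference of state. Mitochondrial share and UMIs per cell do not account for the whole difference either. Here 1777 matched cells per library gave -1.98, with a range of -2.09 to -1.85 over 200 resamplings of the cells. Free RNA of antigen-presenting cells would have to make up 15.3% of wild-type enterocyte RNA at the median of the class II genes. In contrast, 5 abundant markers of macrophages and dendritic cells, Lyz2, C1qa, C1qb, C1qc and Siglech, allow 0.0258% at their median and at most 0.0488%. The ratio of the medians was 0.00169. The profile came from 47 wild-type cells, 14 of them in the unnamed cluster that scored highest for dendritic cells. Less interferon gamma signalling in the knockout epithelium is a candidate explanation that remains open, since 14 interferon gamma inducible genes outside the fixed lists had a median of -1.54 against -0.18 for 15 type I inducible genes, and -0.88 against 0.13 over the shared clusters, but with 1 library per genotype a difference between animals cannot be told apart from the genotype.

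Genes of the regenerating family, Reg1, Reg3a, Reg3b and Reg3g, were higher in knockout enterocytes, with a median of 1.71. Different enterocyte states may account for part of it, since the median over 10 shared clusters was 1.40. Its interval from the spread between clusters, 1.16 to 2.82, reaches both sides of the bound set at 0.75 of the whole. Mitochondrial share and UMIs per cell leave the same doubt, with 1.34 between matched cells, past the bound, and a range of 1.24 to 1.502 that reaches below it. The share of the difference that either accounts for stays open, and in both tests most of it remained on the log2 scale. In knockout T cell-like cells Reg3b stood at 0.899 times the level that free RNA of enterocytes would give, and in wild-type ones at 86.4 CPM against 172 CPM, so its levels there may be free RNA alone, and the genotype stays open as an untested explanation in enterocytes.

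Gm8797 was higher in the knockout library in all 5 classes, by 3.51 to 4.00 on the log2 scale. Free RNA of enterocytes would give 10.6 CPM in knockout T cell-like cells, where 174 CPM were counted, 16.4 times as much, which argues against it. Reads shared with a near-identical transcript remain a candidate explanation: 91.7% of its 460 words of 31 bases occur in Gm1821 and 394 of them in Ubb, which was lower in the same 5 classes, by -0.46 to -0.72. Gm1821 was not found under that name among the counted genes, so its level could not be compared. A strain variant between the animals stays open too, since the reads that would show a variant were not used here. The intervals of 4 of 5 classes held the ratio of all classes summed, 3.61. That cannot decide the question, because the sum includes each class tested and shared reads could also give like ratios in all classes. No biological explanation was tested for this gene.

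Some genes moved in opposite directions in different classes, each by more than 1.5-fold beyond its counting interval, and these differences were not tested. Apoa1 stood at 0.92 in crypt stem/progenitor-like and -0.69 in enterocyte-like cells, 1.61 apart, although its crypt levels of 336 and 635 CPM lay below the 2043 and 1423 CPM that free RNA would give. Zg16 in tuft-like cells stood at -4.68, which was 5.60 below enterocyte-like, 8.39 below crypt-like and 5.98 below T cell-like cells, with 97.7% of its wild-type tuft UMIs in 1 cell. Clca1 stood 6.74 lower in tuft-like than in crypt-like cells and Tff3 4.29 lower in tuft-like than in T cell-like cells, with 96.7% and 92.0% of the wild-type tuft UMIs in 1 cell. Gzma stood 4.40 higher in tuft-like than in crypt-like cells, with 69.4% of the knockout tuft and 71.7% of the wild-type crypt UMIs in 1 cell.

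The barcodes left out by the filters or as predicted doublets also carried Reg3b, at 8360 CPM in 8410 knockout barcodes against 956 CPM in 4727 wild-type barcodes.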

How the results depend on the processing

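Tests with the expected share of doublets left out, over shared clusters and in matched cells were chosen only after the result was seen. Of 45 share values under the alternatives 41 stayed within the counting interval, of 565 list medians of the lists described 383, and of 1542 values of named genes 1172; 356 gene values and 170 list medians moved beyond it, and 14 and 12 whose interval excluded 0 changed sign. Since the lists described were chosen after their values were seen, the count over all lists and classes is given too: 22 values of 13 list medians and 47 values of 39 gene ratios whose interval excluded 0 changed sign. Gsdmd in epithelial cells ranged from -2.05 to -1.85 and the crypt and Wnt median in crypt-like cells from 0.75 to 0.95. The number of cells limits the small classes: tuft-like cells gave no value with the expected share of doublets left out, because fewer than 50 knockout cells remained. For the values below the cause was not tested.

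With the looser cell filter the enterocyte share differed by -14.85 points, the goblet share by 3.45 points, Gsdmd by -1.85 and the enterocyte antimicrobial median was 1.32. The signs of the gut hormone median (-0.21), Cck (-0.82) and Ghrl (-0.21) in enterocytes and of the goblet and mucus median in goblet-like cells (-0.081) reversed. With the stricter filter the enterocyte share reversed to 8.08 points, the T cell-like share differed by -14.07 points, Gsdmd by -2.05, the enterocyte MHC class II median was -1.88, the interferon response median -0.43 and the T cell-like proliferation median -0.60. In enterocytes the peptide and amino acid uptake median (-0.087), the gut hormone median (-0.79), Cck (-1.08), Ghrl (-0.18), Pyy (-3.08) and Cxcl9 (0.056) reversed.

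With the median-of-ratios size factor the class II median was -1.83 in enterocytes and -1.32 in crypt-like cells, the interferon response median -0.51 and the T cell-like proliferation median -0.60. With the mean of CPM per cell the class II median was -1.90 and the proliferation median -0.81, and Ghrl in enterocytes (-0.027) and the goblet and mucus median in goblet-like cells (-0.11) reversed. With at least 100 UMIs per member the class II median was -1.85. Without a minimum and with every member as log2 of CPM + 1 it was -1.77 in enterocytes and -1.33 in crypt-like cells, and the antimicrobial median was 0.31.

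With the expected share of doublets left out the class II median was -1.90 in enterocytes and -1.10 in crypt-like cells. The gut hormone median (-0.15), Cck (-0.92), Ghrl (-0.057) and Nts (-0.42) in enterocytes, Lyz1 (0.57) and Spp1 (1.22) in crypt-like cells, and Mcpt1 (-2.0) and Mcpt2 (-2.26) in T cell-like cells reversed. Over shared enterocyte clusters the class II median was -2.37 and the interferon response median -0.19, and the medians for endoplasmic reticulum stress (-0.059), gut hormone (-0.37), tuft type 2 (0.023) and nuclear oxidative phosphorylation (-0.067) reversed. In matched enterocytes the class II median was -1.98 and the interferon response median -0.26, and the gut hormone (-0.34) and oxidative phosphorylation (-0.033) medians reversed.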

Other observations

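Genes outside the fixed lists that interferon gamma induces, a set chosen after the data were seen, were lower in knockout enterocytes. The guanylate-binding proteins Gbp8, Gbp6 and Gbp4 stood at 46.2 and 1.96 CPM (-4.56), 22.0 and 3.43 CPM (-2.68) and 9.39 and 0.302 CPM (-4.96). The transcription factor Irf8 was at 140 and 64.7 CPM (-1.12), Irgm2 at 96.1 and 45.5 CPM (-1.08), and the checkpoint ligand Cd274 at 10.8 and 3.68 CPM (-1.55). The proteasome activator genes Psme1 and Psme2, also in this set, stood at -0.09 and -0.18. Among genes that type I interferon induces, Ifi44 stood at 0.10, Rtp4 at -0.06 and Xaf1 at -0.05, whereas Usp18 stood at -0.81 and Oasl1 at -0.66.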
